A study of Homo sapiens with 8 samples.

How the data were processed

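RNA from the human bladder cancer line 5637 was profiled as control and after stable knockdown of TRMT61A, a tRNA methyltransferase that places N1-methyladenosine (m1A). Each of the 4 RNA samples, 2 control and 2 knockdown, gave an input library and a library after immunoprecipitation with an m1A antibody, so that the series holds 8 libraries. Groups and replicate numbers were taken from the sample titles and the genotype label. Nothing in the labels says whether replicates were separate cultures. P-values of tests between samples therefore measure only the spread between these samples, which may be technical. Those of gene lists by camera, of expression by peak status and of neighbouring genes compare genes with other genes. They do not measure the spread between samples.

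Per the labels' protocols, total RNA was extracted with TRIzol, depleted of ribosomal RNA, and enriched with a commercial m1A immunoprecipitation kit. The protocols name both a TruSeq stranded kit and a NEBNext directional kit for library construction. Per the submitters' processing notes, the tools used were HISAT2 2.0.4, HTSeq 0.9.1, STAR and edgeR, with build hg38, and their roles and the strand setting of the counting are not given in the sources used here. Per the file headers, the authors deposited raw read counts of the 4 input libraries per gene for mRNA and per transcript for long noncoding RNA (lncRNA). Another 8 columns of normalized values were not used here. Only input libraries measured RNA level, and a test on counts of the immunoprecipitated libraries was not run because these counts were not analysed here.

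The m1A peaks came as 8 lists, 1 per sample and RNA class, so that they were called per sample and not on pooled samples. Per the file headers, each peak has the authors' fold enrichment of immunoprecipitated over input reads, a linear ratio, and a score deposited as 10 times the negative log10 of the peak caller's p. All listed peaks had a fold of at least 2 and a score of at least 50. Their false discovery column was 100 in every row and was not used. Folds and scores were used to describe, rank and filter peaks, by their mean or highest value over the lists and by 1 score limit per RNA class, and were not tested between groups. Input reads at the peaks were not analysed here, so a large fold cannot be split into many immunoprecipitated reads and few input reads. The peak identifiers have the form written by MACS, and its version and settings are not given in the sources used here. The mRNA lists give no strand.

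The mRNA table held 16547 genes with values, of which 16503 gene identifiers matched a reference table of names, and 13362 genes were tested. The lncRNA table held 48055 transcripts, of which 22803 were tested. Of the lncRNA transcripts, 31276 overlap exons of a coding gene on its strand, so that their reads cannot be separated from those of coding isoforms, and 8454 are listed as intergenic only. Total counts per input library were 30046283 to 42177927 for mRNA genes and 1727826 to 2304288 for lncRNA transcripts, so lncRNA values rest on far fewer reads. Positions of mRNA genes came from RefSeq on GRCh38.p14, which has the coordinates of hg38, and positions of lncRNA transcripts and peaks came from the deposited tables.

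Counts were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr with a minimum count of 10, TMM normalization, quasi-likelihood test, no block), on control against knockdown inputs, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes are those implied by the quasi-likelihood F statistic. CPM values are counts scaled by TMM-adjusted library sizes. Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), DESeq2 size factors, the replicate number as a block, no filter, a filter on a mean count of at least 10, and leaving out each input library. The gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Of 24 gene lists, the 21 with at least 5 tested members went through camera with a preset correlation of 0.01, with fry and an estimated correlation beside it. The setting with an estimated correlation has few residual degrees of freedom with so few libraries, so a call lost there is weak evidence. Its estimates were 0.871 for mitochondrially encoded mRNAs, 0.758 for ribosomal, 0.463 for G2/M, 0.386 for histone and 0.271 for cholesterol synthesis genes. For these lists p at the preset value may be too small. Estimates for the other lists past the threshold were -0.063 to 0.046. On simulated counts for the 13362 mRNA genes the test recovered 60% of 1.5-fold, 82% of 2-fold and 100% of 4-fold changes with 10 false calls, and 0 calls were made with no change. For the 22803 lncRNA transcripts it recovered 8%, 48% and 100% at those sizes with 9 false calls, and again 0 calls with no change. Changes were seeded only in rows with a mean count of at least 50, while the median lncRNA count per library was 6 to 8. Recovery at such low counts was not tested. The simulated spread followed the trend over level without differences between genes, so false calls may be understated. Other splits of the real inputs gave 5 and 2 mRNA calls and 0 lncRNA calls.

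Peaks of the 4 lists of an RNA class were merged into regions where they overlapped by at least 1 bp. A region was lost if present in both control lists and neither knockdown list, gained in the reverse case, and kept if present in all 4. The same counts for the other 2 ways to split the 4 lists into pairs gave the background. Alternatives were a score limit at the median of all listed peaks of the class, 50% reciprocal overlap, gene names in place of positions, and 1 replicate number at a time. Genes with a lost region, a gained region or kept regions only were compared in mean log2 fold change with genes without a listed peak, by a two-sided permutation test over genes with 100000 resamples, adjusted over the 3 comparisons. Genes are not independent replicates. Peak analyses used Python 3.11.15 with scipy 1.17.1, and the overlap and permutation steps were tested on simulated data. The planned search for the TRMT6/61A sequence motif and the shares of mRNA peaks in untranslated and coding parts need a genome sequence and exon annotation, which were not used here.

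The rule for named genes took, for mRNA, up to 12 genes per direction with the smallest p among those past adjusted p 0.05 with non-overlapping groups and a mean of at least 5 CPM, the next genes by p being named only as not passing. TRMT61A and the measured m1A machinery were added, with up to 4 members of smallest p from each list with a passing member or a set call. For lncRNA the rule took 8 transcripts per direction by the same rule, 6 known lncRNAs of smallest p and the 3 of highest level. For peaks it took the 6 mRNA and 4 lncRNA regions of highest mean fold among lost and among gained regions, 1 per gene name, the 4 mRNA and 3 lncRNA kept regions of best mean rank, and regions of the m1A machinery. The rule leaves out XIST and Y-linked genes, and XIST and HMOX2, both past the threshold, are named outside it.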

Results

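N1-methyladenosine and RNA levels were profiled in 5637 cells, an established human bladder cancer line, with and without stable knockdown of the methyltransferase TRMT61A, to compare m1A and expression of mRNA and lncRNA. Each group had 2 samples, and each sample had an input library and an m1A immunoprecipitation. The mRNA table held 30046283 and 42177927 counts in control inputs 1 and 2, and 38989448 and 37912238 in knockdown inputs 1 and 2. The lncRNA table held 1727826, 2304288, 2217562 and 2119359 counts in the same order. Peak lists held 6701, 4319, 5793 and 3686 mRNA peaks, and 2588, 1696, 2343 and 1384 lncRNA peaks, in that order.

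The targeted gene was examined first. TRMT61A, the catalytic subunit of the nuclear and cytosolic tRNA m1A methyltransferase (chromosome 14, from 103529196), measured 17.3 ± 3.63 CPM in control and 10.1 ± 4.74 CPM in knockdown inputs (SD, n = 2 each). The 4 libraries stood at 19.8 and 14.7 CPM in control and at 13.4 and 6.71 CPM in knockdown, so that knockdown replicate 1 lay close to control replicate 2. The log2 fold change was -0.78 ± 0.29 (SE) and did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 1.00, unadjusted p = 0.0278). Without knockdown replicate 1 the TRMT61A mRNA level fell by 1.36 on the log2 scale (edgeR adjusted p = 0.00142), and without knockdown replicate 2 the log2 fold change was -0.36 (edgeR adjusted p = 1.00).

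The other 13 measured members of the m1A machinery did not pass. TRMT6, the partner subunit of TRMT61A, stood at 59.9 ± 4.98 CPM in control and 61.4 ± 5.84 CPM in knockdown (SD, n = 2 each). Log2 fold changes were -0.05 for TRMT61B and -0.07 for TRMT10C, both enzymes of mitochondrial m1A, -0.03 for HSD17B10, a partner of TRMT10C, 0.24 for KIAA0391, which encodes the nuclease PRORP, and 0.06 for RRP8, which methylates 28S ribosomal RNA. The demethylases had values of -0.06 (ALKBH3), -0.14 (ALKBH1) and 0.08 (FTO). The reader proteins had values of -0.04 (YTHDF1), -0.03 (YTHDF2), -0.08 (YTHDF3) and 0.03 ± 0.52 (SE, YTHDC1). YTHDC1 was uncertain, at 3.17 and 10.6 CPM in control and 9.83 and 4.37 CPM in knockdown, and leaving out 1 library gave -0.67 to 1.16. As a list, the 14 members did not pass (5 higher and 9 lower, camera adjusted p = 0.398, adjusted p = 0.851 with an estimated correlation). The list passed as lower without knockdown replicate 1 (adjusted p = 0.0261) and was on the higher side without knockdown replicate 2 (adjusted p = 0.369). It also passed when the same inputs were split by replicate number (adjusted p = 0.0283) and crossed (adjusted p = 0.0334), in opposite directions.

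Few mRNAs differed between knockdown and control inputs. Of 13362 genes tested, 5 passed, 1 higher and 4 lower in knockdown, and 441 had an unadjusted p under 0.05. Splitting the same inputs by replicate number also gave 5 genes past the threshold and 1058 at unadjusted p under 0.05, and the crossed split gave 2 and 404. LY6E, a membrane-anchored protein of the Ly6 family (chromosome 8, 143018529 to 143022409), rose from 1.98 ± 0.688 to 24.2 ± 5.10 CPM (SD, n = 2 each), a log2 fold change of 3.64 ± 0.26 (SE, edgeR adjusted p = 0.00212). CNTNAP2, a neurexin-family adhesion protein (chromosome 7, 146116801 to 148420998), fell from 37.5 ± 1.40 to 3.36 ± 0.623 CPM, a log2 fold change of -3.48 ± 0.16 (edgeR adjusted p = 0.000105). NMRAL1, an NADPH-sensing protein (chromosome 16, 4461694 to 4476337), fell from 9.21 ± 0.286 to 1.49 ± 0.083 CPM (log2 fold change -2.63 ± 0.23, edgeR adjusted p = 0.00635). TJP1, which encodes the tight junction scaffold ZO-1 (chromosome 15, from 29699367), fell from 32.3 ± 1.09 to 16.5 ± 0.364 CPM (log2 fold change -0.97 ± 0.11, edgeR adjusted p = 0.0414). HMOX2, the constitutive heme oxygenase, was below the mean of 5 CPM set for named genes and was chosen after its values were seen. Its log2 fold change was -4.11 ± 0.39 (edgeR adjusted p = 0.0117, from -4.76 to -3.67 without 1 library), and it overlaps NMRAL1 on chromosome 16 (4474736 to 4510347), so that reads of this pair may not be separable.

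**Figure D1:**
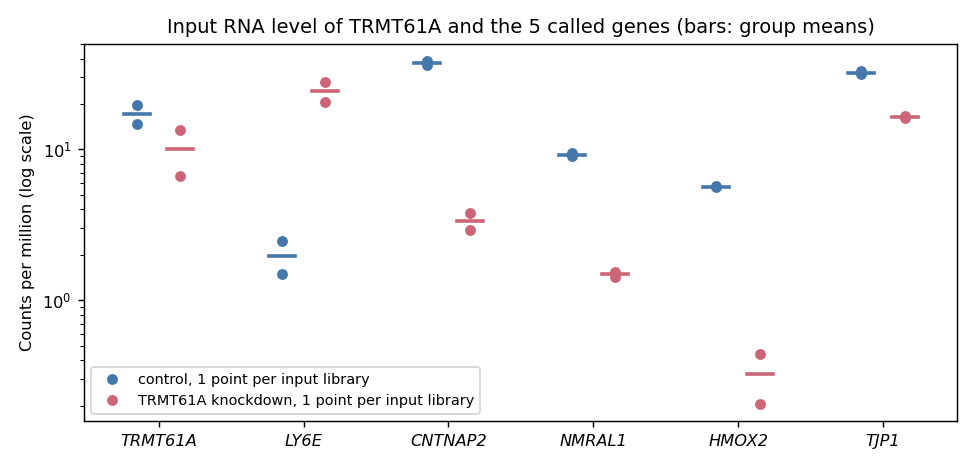
CPM (log scale) of TRMT61A and the 5 mRNA genes past the threshold, with 1 point per input library and a bar at each group mean. The control and knockdown points of the 5 genes are apart, while TRMT61A in 1 knockdown library (13.4 CPM) lies next to 1 control library (14.7 CPM).

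The next genes by p did not pass in the edgeR test, and with DESeq2 those named here did pass except PIR, FTL and APOL6. Among those with higher values were METRNL, a secreted meteorin-like protein (log2 fold change 1.78 ± 0.22 SE, edgeR adjusted p = 0.0562), the xenobiotic receptor AHR (0.47 ± 0.10), the epithelial transcription factor KLF5 (0.36 ± 0.08), the oxidised lipoprotein receptor OLR1 (0.53 ± 0.11) and the translation factor subunit EIF3C (1.16 ± 0.22). Among those with lower values were the splicing factor PUF60 (-2.73 ± 0.39), the olfactory receptor OR2A7 (-0.99 ± 0.16), the nuclear protein PIR (-0.46 ± 0.10), the ferritin light chain FTL (-0.32 ± 0.07), the mTORC1 inhibitor DDIT4 (-0.55 ± 0.12), APOL6 (-0.30 ± 0.07), SRGAP2B (-0.68 ± 0.14) and HIST2H2AA4 (-1.45 ± 0.31). EIF3C, SRGAP2B, OR2A7 and HIST2H2AA4 have near-identical copies in the genome, so their values are uncertain. PUF60 was uncertain too, at 12.5 and 30.1 CPM in control, and leaving out 1 library gave -3.22 to -1.96 for PUF60 and -1.88 to -0.81 for HIST2H2AA4. The number of genes past the threshold was 24 with DESeq2 and 3 with limma-voom, where TJP1 and HMOX2 lost their call, and TJP1 lost it without control replicate 2 as well. It was 17 and 11 without control replicates 1 and 2, and 135 and 32 without knockdown replicates 1 and 2.

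Gene groups were compared next. Markers of basal urothelium were shifted up, with 13 of 16 tested members higher in knockdown (median log2 fold change 0.22, camera adjusted p = 1.04e-08, adjusted p = 0.303 with an estimated correlation). The members of smallest p were the hemidesmosomal collagen COL17A1 (0.46 ± 0.08 SE), the keratin KRT6A (0.42 ± 0.09), the desmosomal cadherin DSC3 (0.38 ± 0.09) and the transcription factor TP63 (0.25 ± 0.08). None passed among all genes in the edgeR test, COL17A1 and KRT6A did with DESeq2, and 4 members passed when adjusted over the list alone. NF-kB and cytokine genes were also shifted up, with 14 of 19 higher (median 0.15, camera adjusted p = 4.4e-10, adjusted p = 0.303 with an estimated correlation) and 7 passing when adjusted over the list alone. Among these were the neutrophil chemokines CXCL5 (0.42 ± 0.08), CXCL1 (0.52 ± 0.11) and CXCL8 (0.49 ± 0.13), and TNFAIP3, a feedback inhibitor of NF-kB (0.57 ± 0.11). CXCL5, CXCL1 and TNFAIP3 passed among all genes with DESeq2, and not in the edgeR test. The smallest adjusted p of fry over all lists was 0.0944.

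Cell division genes of the G2/M phase were shifted down, with 19 of 20 lower in knockdown by small amounts (median -0.16, camera adjusted p = 1.41e-09, adjusted p = 0.54 with an estimated correlation). Cyclin B2 (CCNB2) had a log2 fold change of -0.24 ± 0.08 (SE), topoisomerase TOP2A -0.18 ± 0.07, the proliferation marker MKI67 -0.19 ± 0.08 and the spindle protein NUSAP1 -0.18 ± 0.08, and 0 members passed when adjusted over the list alone. Genes of ATF4 and the unfolded protein response were shifted down as well, 19 of 21 lower (median -0.13, camera adjusted p = 8.18e-08, adjusted p = 0.325 with an estimated correlation). TRIB3, a stress-induced pseudokinase, had -0.58 ± 0.13 and was the 1 member that passed when adjusted over the list alone. The ER chaperone HSP90B1 had -0.24 ± 0.07, the serine synthesis enzyme PSAT1 -0.29 ± 0.10, and asparagine synthetase ASNS -0.66 ± 0.23.

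Cytosolic ribosomal protein genes were lower in 32 of 33 cases (median -0.09, camera adjusted p = 1.13e-07, adjusted p = 0.772 with an estimated correlation), among them RPLP2 (-0.22 ± 0.08 SE), RPL27 (-0.34 ± 0.12), RPS6 (-0.20 ± 0.08) and RPS2 (-0.21 ± 0.09). Histone genes were lower in 14 of 15 cases (median -0.10, camera adjusted p = 0.000312, adjusted p = 0.629 with an estimated correlation), led by HIST1H1C (-0.24 ± 0.07) and HIST1H4H (-0.23 ± 0.09). Shifts down with larger p also passed for mesenchymal and matrix genes (median -0.20, camera adjusted p = 0.02), immediate early and heat shock genes (0.02), mitochondrially encoded mRNAs (0.0296) and cholesterol synthesis (0.0357). In that order, adjusted p = 0.54, 0.527, 0.835 and 0.835 with an estimated correlation. Members of these lists with low p included ZEB1 (-2.22, at under 1 CPM), HSPB1 (-0.46), DNAJB1 (-0.21), MT-ND6 (0.21), MT-CO1 (-0.20), FDFT1 (-0.18) and SREBF2 (-0.15), and 0 of them passed. The call was kept without each of the 4 libraries for the basal, NF-kB, G2/M and ATF4 lists. The ribosomal list lost it without knockdown replicate 2 (adjusted p = 0.712), and the remaining 5 lists each lost it without at least 2 libraries.

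Of 21 lists tested, 11 did not pass. Luminal urothelial markers had 7 of 15 members higher (median -0.02, mean 0.02, camera adjusted p = 0.902). The m1A machinery had an adjusted p of 0.398, tRNA modification enzymes 0.891, m6A machinery 0.749, p53 targets 0.516 (median 0.04, mean -0.02), interferon-stimulated genes 0.158, glycolysis and hypoxia 0.246, MYC targets 0.188, G1/S genes 0.0857 and nuclear OXPHOS genes 0.0857. Besides the m1A list, 6 of the 11 passed without 1 library. Without control replicate 1, G1/S genes passed as higher (adjusted p = 0.0326) and fibroblast markers as lower (0.0012), and without control replicate 2 interferon-stimulated genes passed as higher (0.00271). Without knockdown replicate 1, interferon-stimulated genes passed as higher (0.000919), and MYC targets (7.99e-08) and nuclear OXPHOS genes (0.00273) as lower. Without knockdown replicate 2, G1/S genes (0.00152) and MYC targets (0.000285) passed as higher, and luminal (0.0279) and fibroblast markers (0.0219) as lower. Markers of other cell types were measured as well. Fibroblast markers had a median of 2.55 CPM over 6 tested members (camera adjusted p = 0.095), the highest being the collagen COL1A1 at 33.3 ± 1.13 CPM in control and 33.6 ± 8.27 in knockdown (SD, n = 2 each). The single tested immune marker, CD14, measured 0.57 ± 0.338 CPM in control and 0.71 ± 0.38 in knockdown (SD, n = 2 each), and the highest of 4 endothelial markers, VWF, 1.39 ± 0.342 and 1.17 ± 0.849 CPM.

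**Figure D2:**
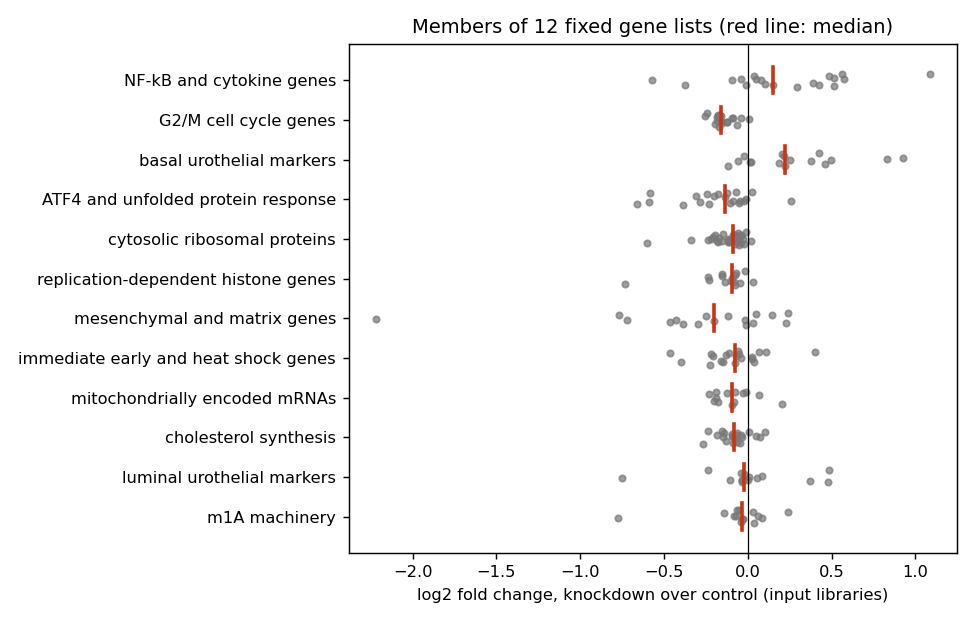
Log2 fold change of knockdown over control inputs for each tested member of 12 gene lists, with 1 point per gene and a red line at the list median. Medians run from -0.20 (mesenchymal and matrix genes) to 0.22 (basal urothelial markers).

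Among lncRNA transcripts, 5 of 22803 passed, 1 higher and 4 lower in knockdown. With transcripts summed per gene name, 4 of 12748 names passed, 1 higher and 3 lower. Values given for a named lncRNA, XIST included, are those of 1 transcript and not of the whole gene. RN7SL4P, a copy of the signal recognition particle RNA on chromosome 3 (15738514 to 15738809), rose from 3869 ± 708 to 8132 ± 399 CPM (SD, n = 2 each), a log2 fold change of 1.07 ± 0.10 (SE, edgeR adjusted p = 1.03e-06). It belongs to a family of near-identical copies and is uncertain, since all RN7SL names together took 9.91% and 9.23% of lncRNA counts in control and 9.81% and 8.28% in knockdown. The taste receptor pseudogene TAS2R15P on chromosome 12 (10964424 to 10965352) fell from 26.2 ± 7.12 to 1.90 ± 0.047 CPM (log2 fold change -3.75 ± 0.55, edgeR adjusted p = 0.00257). A noncoding transcript of TAF4, the gene of a TFIID subunit, had 68 counts over the control inputs and 0 in knockdown, which is at least 24.5-fold lower at a floor of 3 counts over the group (edgeR adjusted p = 0.00257). AC011330.1, which shares exons with CATSPER2, fell from 103 ± 32.7 to 34.6 ± 1.82 CPM (log2 fold change -1.55 ± 0.24, edgeR adjusted p = 0.00457). XIST, the lncRNA of X chromosome inactivation, is left out by the naming rule and was chosen after its values were seen. It had 73 counts over the control and 2 over the knockdown inputs, 39.5-fold lower (95% exact binomial interval 10.5 to 332.1, counting error only; edgeR adjusted p = 0.00521).

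Next by p, and not passing, were higher values of CYTOR, an oncogenic lncRNA (13.3 ± 0.062 CPM in control and 40.7 ± 11.7 in knockdown, SD, n = 2 each), AC233968.1, AP000904.1, AC080080.1, AC245407.2, RPL21P119 and a noncoding transcript of BRAP, with log2 fold changes of 1.06 to 3.48. The highest value, that of RPL21P119, rests on knockdown replicate 2 (86 counts against 12 in knockdown replicate 1) and was 1.43 without it, and AC245407.2 ran from 1.35 to 2.48 without 1 library. Lower values were seen for LINC00665 (49.0 ± 4.26 and 18.5 ± 4.91 CPM), ZNF337-AS1, FP236241.1 and a noncoding transcript of FASN, with log2 fold changes of -2.90 to -1.40. The lowest value, that of ZNF337-AS1 (7 and 1 counts in knockdown), ran from -4.75 to -2.13 without 1 library, and that of FP236241.1 from -3.21 to -2.07. Among known lncRNAs, LINC00511 had 0.33 ± 0.11 (SE), SNHG3 -0.43 ± 0.18, FTX -0.81 ± 0.36, JPX -1.22 ± 0.54 and KCNQ1OT1 -0.23 ± 0.10, and these 5 did not pass. Leaving out 1 library moved SNHG3 to between -0.92 and -0.07, FTX to between -1.10 and -0.51, JPX to between -2.29 and -0.61 and KCNQ1OT1 to between -0.38 and -0.08. The most abundant, NORAD, NEAT1 and MALAT1, had log2 fold changes of 0.00, -0.06 and 0.02. The number of transcripts past the threshold was 24 and 22 without control replicates 1 and 2, and 32 and 18 without knockdown replicates 1 and 2, and AC011330.1 lost its call without control replicate 1 and the TAF4 transcript and XIST without control replicate 2. With limma-voom, TAS2R15P, the TAF4 transcript and XIST did not pass, and with DESeq2 XIST did not (adjusted p = 0.075). The log2 fold change of XIST, -5.11 ± 0.82 (SE), ran from -8.20 to -4.22 without 1 library.

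The number of m1A peaks was lower in knockdown within each replicate number. In mRNA, the control lists held 5510 ± 1684 peaks and the knockdown lists 4740 ± 1490 (SD, n = 2 each), a ratio of 0.860, with 0.865 for replicate 1 and 0.853 for replicate 2. In lncRNA they held 2142 ± 631 and 1864 ± 678 peaks, a ratio of 0.870, with 0.905 and 0.816. Replicate 1 lists were 1.55 times as long as replicate 2 lists in control and 1.57 times in knockdown for mRNA, so the difference between groups was smaller than the spread within them. An exact two-sided permutation test, which did not pair samples by replicate number, gave p = 0.667 for both classes. The smallest p this test allows here is 0.333. Peak numbers were not adjusted for the depth of the immunoprecipitated libraries, which was not analysed here.

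Most m1A regions with a fold over 1000 lay near tRNA genes, and 10 of 16 such regions in mRNA and 19 of 25 in lncRNA were listed in every sample. The highest mean folds were those of METTL26 and MCRIP2 in lncRNA, neither listed in every sample, and they were chosen after their values were seen. Both regions lie near the same glycine tRNA gene, so they may be 1 site with other bounds. Sites found in every sample may therefore be more than these counts of regions. The kept mRNA regions of best rank were in SHF (chromosome 15, 45200727 to 45201175), TRIM41 (chromosome 5, 181222499 to 181222652), ERCC1 (chromosome 19, 45478736 to 45478828) and ILF2 (chromosome 1, 153670918 to 153671048), with mean authors' folds of 63129, 40193, 8583 and 3977 over the 4 samples. Folds differed between samples, and not in 1 direction. In ILF2 they were 5562 and 4918 in control and 2701 and 2728 in knockdown, and those in SHF and ERCC1 were also lower in both knockdown samples. In TRIM41 they were 37391 and 19679 in control and 51113 and 52589 in knockdown. Folds were not tested between groups. The region in SHF covers a histidine tRNA gene, and each of the other 3 has a tRNA gene within 500 bp. The kept lncRNA regions of best rank, in AJ003147.2, AJ003147.1 and a noncoding transcript of FCGR2A, likewise lie within 500 bp of tRNA genes. Their folds were higher in both knockdown samples than in both control samples. Of regions over 1000-fold, 13 of 16 in mRNA and 21 of 25 in lncRNA had a tRNA gene within 500 bp, against 0 of 9125 and 2 of 3886 regions of up to 10-fold. Of 27 mRNA and 47 lncRNA regions near a tRNA gene, 18 and 34 were kept, 0 were lost in either class, and 2 mRNA regions were gained. Kept regions had higher folds than lost ones overall (1107 kept and 192 lost mRNA regions were between 10-fold and 100-fold, 173 kept and 508 lost up to 10-fold), and the counts near tRNA genes were not matched on fold. The window of 500 bp was chosen after the strongest peaks were seen. Fewer of these regions covered a tRNA gene. In each list 2 of the 10 to 13 mRNA regions over 1000-fold did, and 6 to 9 of the 13 to 18 lncRNA regions.

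**Figure D3:**
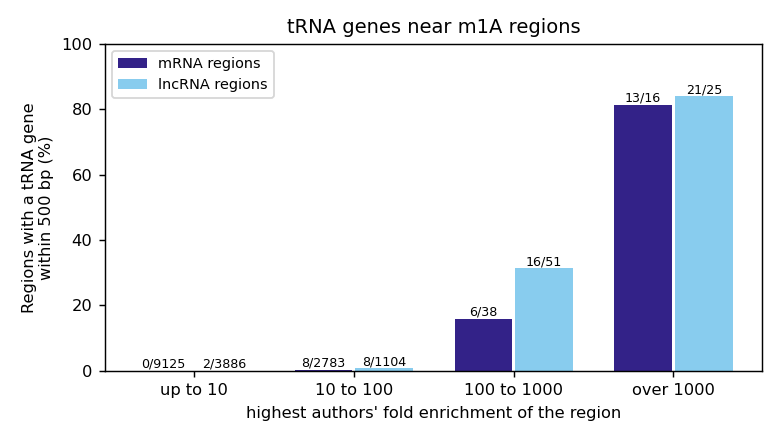
Percentage of m1A regions with a tRNA gene within 500 bp, by the highest fold enrichment the authors gave the region, with the number of such regions over all regions above each bar. The share is 81.3% (mRNA) and 84% (lncRNA) over 1000-fold.

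More mRNA regions were lost than gained. The control lists of both RNA classes were also longer within each replicate number, and numbers of lost and gained regions were not adjusted for list length. Of 11962 merged regions, 701 were in both control lists only and 274 in both knockdown lists only, while 1320 were in all 4 and 7301 in a single list. Splitting the lists by replicate number put 476 regions in both replicate 1 lists only and 137 in both replicate 2 lists only, and the crossed pairs gave 335 and 228. Overlap of the control lists (Jaccard 0.346) was above that of the knockdown lists (0.265) and of any control list with a knockdown list (0.251 to 0.321). Within a single replicate number, 4193 regions were in control only and 3266 in knockdown only for replicate 1, and 2370 and 1738 for replicate 2.

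The lost mRNA regions of highest fold were in TCEA2, a transcription elongation factor (chromosome 20, 64063481 to 64063949), the carbonic anhydrase-related CA11 (chromosome 19, 48645566 to 48646312), the nonmuscle myosin MYH14 (chromosome 19, 50289436 to 50289648), the Ran GTPase activator RANGAP1 (chromosome 22, 41256711 to 41256824), the interleukin receptor IL17RA (chromosome 22, 17104726 to 17104810) and prothymosin PTMA (chromosome 2, 231712804 to 231713541), with authors' mean folds of 23.2 to 101. The gained regions were in TCEA2 (chromosome 20, 64063144 to 64063384), the endosomal tethering protein VPS53 (chromosome 17, 714623 to 714856), C8orf37 (chromosome 8, 95269077 to 95269201), the semaphorin receptor PLXNA3 (chromosome X, 154458281 to 154458428), the fatty acid transporter SLC27A4 (chromosome 9, 128340646 to 128340838) and cathepsin CTSZ (chromosome 20, 59006986 to 59007247), with mean folds of 26.3 to 67.1. The lost and gained regions of TCEA2 lie side by side, so that they may be 1 site with other bounds. The gained regions of C8orf37 and SLC27A4 are those near tRNA genes, and the place of C8orf37 rests on knockdown replicate 1 (fold 78.7, against 3.54 in knockdown replicate 2).

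Of the 14 genes of the m1A machinery, at least 5 had a listed mRNA peak. Peaks were searched under PRORP and not under KIAA0391, so a peak listed as KIAA0391 would be missed. Of all 13362 tested genes, 6512 had no listed peak, and the shares were not compared by a test. YTHDC1 had a lost region (chromosome 4, 68337027 to 68337450) and a kept one (68349726 to 68350089), and YTHDF3 had a kept region (chromosome 8, 63168553 to 63168901). TRMT61A had a peak in knockdown replicate 2 alone (chromosome 14, 103534761 to 103535847), while FTO and HSD17B10 had peaks in control replicate 1 alone. A noncoding transcript of YTHDF2 had a peak in control replicate 2 alone.

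In lncRNA, 291 regions were lost and 99 gained of 5066, with 409 kept. The split by replicate number gave 158 and 53, and the crossed split 133 and 94. Lost regions of highest fold were in FP236383.3 (chromosome 21, 8437991 to 8438551), a noncoding transcript of VPS53 (chromosome 17, 714213 to 714513), AL109840.2 (chromosome 20, 58980901 to 58981169) and the ribosomal protein pseudogene RPL5P17 (chromosome 5, 85464993 to 85465310). Gained regions were in the mitochondrial pseudogene MTND4P12 (chromosome 5, 134926660 to 134928036) and noncoding transcripts of PPP1R12C (chromosome 19, 55096077 to 55096335), NOP53 (chromosome 19, 47753937 to 47754891) and STUB1 (chromosome 16, 680419 to 681068). The place of FP236383.3 rests on control replicate 1 (fold 510, against 4.94 in control replicate 2). The lost VPS53 region lies close to the gained mRNA region of the same gene, and values of the pseudogenes are uncertain because near-identical copies share reads.

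**Figure D4:**
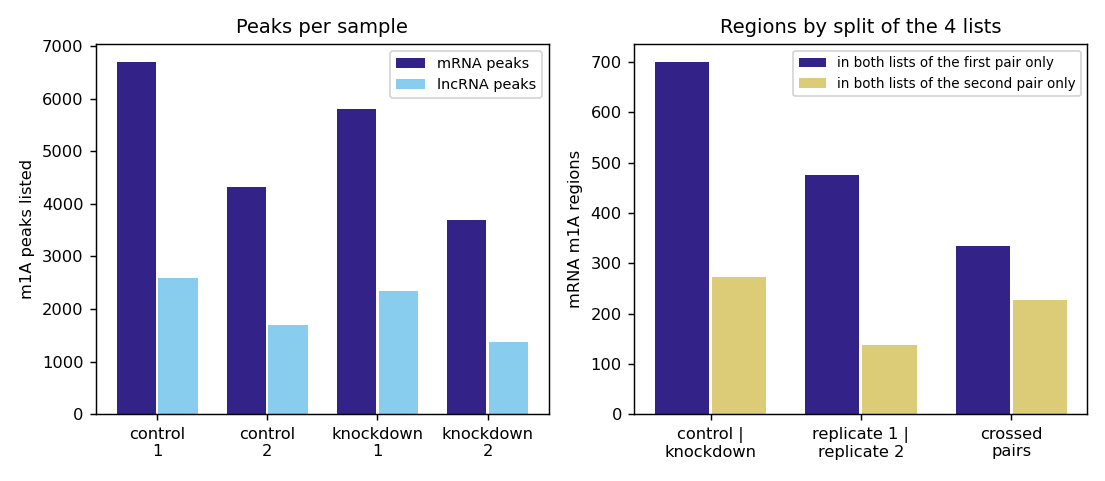
Left, m1A peaks listed per sample for mRNA and lncRNA. Right, mRNA regions found in both lists of 1 pair and neither of the other, for the 3 ways to pair the 4 lists; the control and knockdown pairs gave 701 and 274, the replicate numbers 476 and 137, and the crossed pairs 335 and 228.

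Expression did not differ past the threshold by peak status in the main permutation test. The 597 tested mRNA genes with a lost region had a mean log2 fold change 0.01 below that of the 6512 genes without a peak (difference -0.0074 ± 0.0132 SE, permutation adjusted p = 0.629). The difference was -0.0231 ± 0.0225 for 222 genes with a gained region (permutation adjusted p = 0.524) and -0.0175 ± 0.0083 for 648 genes with kept regions only (permutation adjusted p = 0.524). Kept genes had a smaller SD (0.177) than genes without a peak (0.365), and the permutation treats these as alike, unlike the SE. By gene name the kept difference was -0.0233 ± 0.0065 (permutation adjusted p = 0.0534), so a small difference for kept genes is not excluded. An alternative compared kept genes with genes without a peak in the same of 10 bins of mean level. There the kept difference was -0.01 (permutation adjusted p = 0.736). In lncRNA, differences for 133 transcripts with a lost, 35 with a gained and 154 with kept regions were -0.0237 ± 0.0426, -0.0533 ± 0.0993 and -0.0252 ± 0.0411 (permutation adjusted p = 0.611 each). Of the genes past the expression threshold, LY6E had a gained region (chromosome 8, 143018482 to 143018586), and HMOX2 had a lost one (chromosome 16, 4505484 to 4505610). In both, that region was listed only in the group with the higher level. HMOX2 had another region (chromosome 16, 4476340 to 4476665), listed in both control samples and in knockdown replicate 1 (fold 12.11), so its peaks did not all follow its level. Without knockdown replicate 2 the mRNA differences for lost, gained and kept genes turned to 0.053, 0.0433 and 0.0532 (permutation adjusted p = 0.0449, 0.268 and 0.0449), and without knockdown replicate 1 to 0.0138, 0.0016 and 0.0009 (permutation adjusted p = 0.974 each). The lncRNA difference for lost regions turned to 0.143 without control replicate 1 and 0.136 without knockdown replicate 2 (permutation adjusted p = 0.123 and 0.158).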

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

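Leaving out a library leaves 1 sample in a group, which is then assumed to vary like the other group. The TRMT61A mRNA level kept its direction, from -1.36 (past the threshold, without knockdown input replicate 1) to -0.36 without knockdown input replicate 2. With 5 mRNA genes in the edgeR test, the count was 15 with the replicate number as a block, 24 with DESeq2, 3 with limma-voom, 14 with no filter, 91 at unadjusted p under 0.05 and 2-fold, and 11 to 135 without 1 library; the cause was not tested. With 5 lncRNA transcripts it was 22 with the block, 24 with no filter, 585 at unadjusted p and 2-fold, and 18 to 32 without 1 library; the cause was not tested. The replicate numbers were not treated as pairs in the main test. Deviations of same-numbered inputs had a correlation of 0.0475 for mRNA and 0.022 for lncRNA. Structure by replicate number is not excluded by this. The split by number gave 1058 mRNA genes at edgeR unadjusted p under 0.05, against 441 in the real split. Peak lists of replicate 1 were longer than those of replicate 2 in both groups. Of 10 gene lists past the threshold, 0 passed with an estimated correlation. Directions turned without control input replicate 1 for mesenchymal genes (adjusted p = 0.997, range without 1 library 2.46e-06 to 0.997) and mitochondrially encoded mRNAs (0.129, range 1.38e-08 to 0.129). They turned without knockdown input replicate 2 for cholesterol synthesis (0.754, range 0.000579 to 0.754) and MYC targets (0.000285, range 7.99e-08 to 0.694); the cause was not tested. With the block METRNL, PUF60, COL17A1, DDIT4 and CXCL1 passed, and of the lncRNAs CYTOR, LINC00665, AC233968.1, RPL21P119 and ZNF337-AS1. Of 95 named genes, 62 kept their side of the threshold under every alternative run for them. Direction was compared only where the main fit or the alternative passed. Some genes that did not pass changed direction, such as FN1 (-0.84 to 0.14 without 1 library) and NEAT1 (-0.22 to 0.11).

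For mRNA m1A peaks lost and gained, the stricter score, which leaves fewer peaks, gave 397 and 121 regions, and gene names gave 424 lost. For lncRNA m1A peaks lost and gained it gave 181 and 34, a ratio of 5.32. With 1 replicate number alone, where 1 list per group suffices, mRNA gave 2370 to 4193 lost and 1738 to 3266 gained, and lncRNA 1044 to 1770 lost and 729 to 1520 gained. The ratio of lost to gained was 2.56 in mRNA and 2.94 in lncRNA, and within replicate numbers its geometric mean was 1.32 (1.28 to 1.36) and 1.29 (1.16 to 1.43). Without 1 input, the expression difference ran from -0.0409 to 0.053 for mRNA genes with a lost region and from -0.0544 to 0.0532 for those with kept regions, both highest without knockdown input replicate 2; the cause was not tested. The motif, mRNA peak positions and immunoprecipitated counts were not run, nor were the planned pseudocounts, which were for normalized values. The prior count of 2 in the log2 CPM behind both correlations of deviations, and those built into the fitted log2 fold changes, were not varied. Simulated 2-fold changes, seeded in rows with a mean count of at least 50, were recovered in 82% of mRNA and 48% of lncRNA cases. The spread between replicates was larger in lncRNA (common biological coefficient of variation 0.224 against 0.112), and the part due to depth was not tested.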

Other observations

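The tests on lncRNA peak positions, on genes far apart between replicates, on whether neighbouring genes switch in the same libraries and on other splits of the m1A lists were chosen only after the results were seen. Peaks on lncRNA transcripts lay more often near the start than near the end of the transcript. Among peaks on transcripts spanning at least 3000 bp, 46.6% and 50% in the control lists and 44.9% and 54.1% in the knockdown lists had their midpoint within 500 bp of the 5 prime end (95% exact binomial intervals 44.1 to 49.1, 46.8 to 53.2, 42.2 to 47.6 and 50.5 to 57.6). In the same lists 12% to 15.5% lay as close to the 3 prime end. Spans are genomic and include introns, while both ends are exonic, so an even spread over the span is no fair expectation. The control and knockdown lists overlapped in these shares. Peaks on transcripts sharing exons with a coding gene made up 53% to 58.8% of each list, and intergenic transcripts 21.9% to 27.6%.

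The mRNA genes past the threshold were set against genes with large differences between libraries. Of 10618 genes with a mean of at least 5 CPM, 3 (CNTNAP2, LY6E and NMRAL1) were over 4-fold apart in every pair of libraries across the groups, against 1 and 2 across the other splits. By a looser criterion, 16 were over 4-fold apart between replicates of 1 group, such as the proteasome subunit PSMB3 (5.43 and 58.8 CPM in control). Of the 18 placed genes with either kind of difference, 9 had another within 1 Mb. The highest value in 10000 random sets was 7 (permutation p = 0.0001, the smallest these sets can give). Of 5 neighbouring pairs, 1 (PSMB3 and PIP4K2B) was high in the same libraries, so switching together is not shown for most of these pairs. HMOX2 had a mean under 5 CPM and was outside these pairs. It fell from 5.66 to 0.324 CPM, and the overlapping NMRAL1 fell from 9.21 to 1.49 CPM, so this pair changed together. Whether stretches of neighbouring genes switch together stays open. Reads assigned to different near-identical copies of a locus may contribute and cannot be told apart from an effect of the knockdown, as 3 splits are too few.

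The gene lists past the threshold were set against the other splits of the inputs. Splitting by replicate number put 13 lists past the threshold, the crossed split 8, and the real split 10. Differences between single libraries irrespective of group may therefore account for the number of lists called. The NF-kB list was called in the split by number (adjusted p = 0.00116) and the G2/M list in the crossed split (adjusted p = 0.00182), and the ribosomal list in both. The basal urothelial, ATF4 and immediate early lists were past the threshold in the real split and in neither other split, and an effect of the knockdown on them stays open.

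The lost mRNA regions were weighed for technical sources. Lost regions were not gathered at the calling limit of the control lists, with a median score percentile of 49.6, although kept regions stood at 82.3. A dropout of weaker peaks is not excluded by this. A percentile near the middle is that of a typical listed peak, and 7301 of all 11962 regions were in a single list. Lost regions also have no score in the knockdown lists. Shifted bounds or a listing under the other RNA class were argued against as the whole source, since 7.1% of the 701 lost regions lay within 500 bp of a knockdown peak of either class. Differences between lists irrespective of group cannot be told apart from the knockdown, since another split of the lists gave up to 476 regions, and 3 splits are too few to exclude chance. A loss of m1A after TRMT61A knockdown stays open as well, untested without sequence.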
